A study of Rattus norvegicus with 23 samples.

How the data were processed

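Libraries of polyadenylated RNA from rat myocardium were sequenced on an Illumina platform, per the labels' protocols. The submitters' processing notes name Partek and the rat genome build rn6, without versions or roles. The aligner, the counting tool, the annotation, the scaling and the statistical model are not given in the sources used here, nor whether counting used strand. The first kind of deposited values is a signal, the normalized count per gene and library for the 12-week groups, per the file headers. In each library nearly all low values were whole multiples of 1 step, the library's smallest value, and none was 0. A value was therefore taken as the number of reads plus 1, times the step, which was not checked for higher values. Among values of up to 20 steps, between 97.2% and 98.6% per library lay within 0.1 of a whole number. The authors also deposited 2 tables of comparisons, for 6 and for 12 weeks, with a p-value and a step-up false discovery rate per gene, per the file headers. These tables give the linear ratio of MI+TRD to MI, per the file headers, together with the authors' signed fold change (the ratio, or minus its reciprocal below 1) and the least-squares mean per group. The false discovery rates equalled Benjamini-Hochberg values of the deposited p-values. The means of the authors' 12-week table equalled means of the values per library after another factor for each library, between 0.953 and 1.08, so the authors' comparison used a slightly different scaling. Values per library at 6 weeks were not used here.

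The table of values per library held 10723 genes, each reaching at least 31 reads in 1 library, and no column without a sample. The recovered reads numbered 7197118 to 10304156 per library, and a count of 0 allows up to 3 reads, for counting error only. The column totals were 450798 ± 58012 in MI and 379983 ± 11013 in MI+TRD (SD, n = 6 each; exact permutation p = 0.00433). The 3 ribosomal RNA entries took 6.13% ± 3.96 and 2.82% ± 1.08 of the total (exact permutation p = 0.0758). The smallest p that the 462 splits of 6 against 6 libraries allow is 0.00216. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 15.0), and Pearson's r of log2 values between libraries lay between 0.852 and 0.978. The labels name separate samples of 6 per group at 12 weeks but no animal identifiers, so p-values measure the spread between these samples.

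The groups, tests, gene lists, rule for named genes and most alternatives were set before the data were examined. At 12 weeks the test was limma with a trended prior (eBayes) on log2(value + pseudocount), two-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount was 0.208 deposited units, and genes with a mean share of the column totals equal to at least 0.415 deposited units were kept, 10655 in all. Fold changes are on the log2(value + pseudocount) scale, which understates the change of genes with low values. Relative values are a fold change minus the median over all genes tested. On the recovered reads, edgeR's quasi-likelihood test called 0 genes and DESeq2 called 21. A Wilcoxon test, exact for genes whose values all differed, was run on the deposited values. Of 40 gene lists 39 were tested, since no transcript of the mitochondrial genome was in the table. Camera used a preset correlation of 0.01, and camera with an estimated correlation, rank-based camera and fry were run beside it. Scores per library, the mean log2 value of a list's members, were compared by two-sided exact permutation over all 924 assignments, adjusted over 16 marker and technical lists. Some genes stood in more than 1 list: among lists called, Efemp1 in both the epicardial and the matricellular list, and the C1q genes in both the macrophage and the complement list. For the authors' deposited tables, a list's median log2 ratio was placed among 10000 random lists of its size drawn from 20 bins of mean level.

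The genes named at 12 weeks were to be the 12 highest and 12 lowest fold changes past the threshold with that direction in at least 5 of 6 MI+TRD libraries, filled by the smallest p where fewer passed. As none passed, all 24 are genes with the smallest p. Another 15 genes of cardiac stress and scar were named in any case, with up to 3 members of each list by smallest p, and at 6 weeks 10 genes each way from the authors' deposited table by the same rule. Some members of the lists are not reported here by name, although they stayed in every count and test of their lists. The genes called by DESeq2 alone were named after their values were seen. Coordinates are those of the deposited table. Overlapping genes and near-identical copies cannot be separated without the counting rules.

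The steps were tested on simulated reads for the 12-week comparison, drawn for 10625 genes from the real means and library sizes. Of 50 genes changed by each fold, limma recovered 16% at 1.5-fold, 44% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 19 of 145 calls were false. A simulated respiratory chain list lowered 1.5-fold was called, with 2 other lists. Each gene was drawn independently of the others, so the simulation could not check the set test for lists whose members move together. In the real data the estimated correlation between members was 0.749 for the respiratory chain list and 0.431 for the epicardial list. Alternatives covered the pseudocount, the filter, the scaling, robust and weighted fits, a replicate block, each library left out in turn, the thresholds and the set tests. Chosen after seeing the data were the factors of the authors' table, totals without ribosomal RNA, atrial markers as a covariate, the removal of a trend with gene span, and fits without 3 libraries with Myl7 above 100 (MI replicates 2 and 5, MI+TRD replicate 2) or without the 3 lowest in genes spanning up to 2 kb (MI+TRD replicates 1, 4 and 5). Other splits of the libraries were drawn 100 times from 462. They had been drawn once before with another seed, and the counts recorded from that draw, those at an unadjusted p and of gene lists, fell on the same side of the threshold. Span is the distance from a gene's start to its end in the deposited table, not the transcript's length. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.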

Results

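Messenger RNA was sequenced from the myocardium of Sprague-Dawley rats after myocardial infarction (MI), made by tying off the left coronary artery. Other rats had the same infarction and then a second operation that implanted a device, named TRD in the labels and not described further there (MI+TRD). The 23 libraries fell into 4 groups, with 6 of MI and 6 of MI+TRD at 12 weeks and 6 of MI and 5 of MI+TRD at 6 weeks. The replicates are taken to be separate rats, although the labels give no animal identifiers. Values per library covered 10723 genes in the 12 libraries of the 12-week groups, and the reads inferred from them came to between 7197118 and 10304156 per library. The 6-week groups entered through the authors' deposited table of that comparison, since values per library at 6 weeks were not used here.

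The 12-week comparison asked how myocardium with the device differed from infarcted myocardium without it. The gene with the smallest p among those higher was Tnfrsf11b (chromosome 7, 93798580 to 93826587, rn6), which encodes osteoprotegerin, a secreted decoy receptor for RANKL. Its normalized count was 1.29 ± 0.512 (SD, n = 6) in MI and 9.78 ± 8.95 (SD, n = 6) in MI+TRD, a log2 fold change of 2.30 (SE 0.49). The smallest p among lower genes belonged to RT1-T24-3 (chromosome 20, 3226391 to 3233695), a class I MHC gene of a family of near-identical copies that can share reads, with 12.4 ± 3.25 (SD, n = 6) in MI and 5.73 ± 1.30 (SD, n = 6) in MI+TRD. Both were displaced the same way in 6 of 6 MI+TRD libraries, and neither passed the test over all genes (limma adjusted p = 0.133).

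Other genes at the head of the ranking by p were likewise displaced in 6 of 6 MI+TRD libraries at a limma adjusted p of 0.133, and none of them passed. On the higher side, Selenop, the plasma selenium carrier, measured 205 ± 41.9 in MI and 306 ± 49.1 in MI+TRD (SD, n = 6 each). Ncoa4, the receptor that delivers ferritin to lysosomes, measured 59.3 ± 3.95 and 80.3 ± 12.7. Jak2, a kinase of cytokine receptors, measured 10.1 ± 2.19 and 16.0 ± 3.86. The orphan receptor Gpr22, the secreted guidance factor Sema3c, the protein kinase C substrate Marcks and the nuclear receptor coactivator Pnrc1 had log2 fold changes of 1.60 (SE 0.43), 1.13 (SE 0.31), 0.83 (SE 0.23) and 0.67 (SE 0.15). The deadenylase Cnot6l measured 6.09 ± 2.71 and 11.3 ± 1.34. The log2 fold changes were 1.02 (SE 0.27) for Tmtc3, 0.87 (SE 0.24) for the palmitoyltransferase Zdhhc20 and 0.82 (SE 0.23) for the signal peptidase subunit Spcs3.

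On the lower side, Traf2, an adaptor of TNF receptors, measured 12.5 ± 1.37 in MI and 7.22 ± 1.22 in MI+TRD (SD, n = 6 each). Mapk12, the p38-gamma kinase, measured 13.7 ± 2.02 and 8.35 ± 0.840. Myh7b, a slow myosin heavy chain, measured 176 ± 42.0 and 98.2 ± 16.1. Pmpca, a subunit of the peptidase that trims proteins imported into mitochondria, measured 50.8 ± 6.25 and 29.0 ± 8.65. The log2 fold changes were −0.99 (SE 0.19) for the transcription factor Tcf15, −0.82 (SE 0.16) for Bod1, −0.67 (SE 0.14) for the matrix protein gene Egflam and −0.60 (SE 0.12) for the coronin Coro6. They were −0.68 (SE 0.14) for the caveolar protein Cavin3, −0.68 (SE 0.14) for the lysosomal transporter Spns1 and −1.05 (SE 0.23) for the small GTPase Rasl11b. Another 5 higher and 47 lower genes at an unadjusted limma p below 0.05 carried only locus identifiers.

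With limma, 0 of 10655 genes passed an adjusted p of 0.05, while 298 were higher and 2033 lower at an unadjusted p below 0.05, against 533 in all by chance. At an adjusted p below 0.05 the Wilcoxon test called 0 genes (lowest adjusted p 0.127). Its exact p cannot fall below 0.00216 with 6 against 6 libraries, so a count of 0 over 10655 genes says little. The count at an adjusted p below 0.05 was 0 with edgeR on recovered reads and 21 with DESeq2 on recovered reads. Of these 21, Tnfrsf11b had a DESeq2 log2 fold change of 3.08 (adjusted p = 1.48e-05). The others higher were Upk1b, Ncoa4, Pnrc1, C3, Krt8, Jak2, Selenop, Dyrk2, Msln, Nedd9 and Slit3, and those lower were RT1-T24-3, Mapk12, Myh7b, Traf2, Cavin3, Tcf15, Gp1bb, Rex1bd and Spns1. The median gene lay at −0.14 (log2) in the deposited scale, so from here on limma fold changes of genes and list medians are relative to it unless stated. Group means and counts of list members at a p or adjusted p stay on the deposited scale. On it 19.1% of all genes were lower at an unadjusted p below 0.05. Without MI replicate 4 the count of higher genes was 190. The split of higher against lower genes moved with the scaling, to 798 against 878 with median ratios, 701 against 1042 with quantile normalization and 1208 against 412 with equal totals. It was 899 against 704 with equal totals after leaving out ribosomal RNA, 715 against 657 with a trend over gene span removed, and 852 against 744 with edgeR. With no rescaling, it was 285 against 1031 without MI+TRD replicates 1, 4 and 5, 149 against 1460 with library weights and 238 against 1330 with atrial markers as a covariate.

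**Figure D1:**
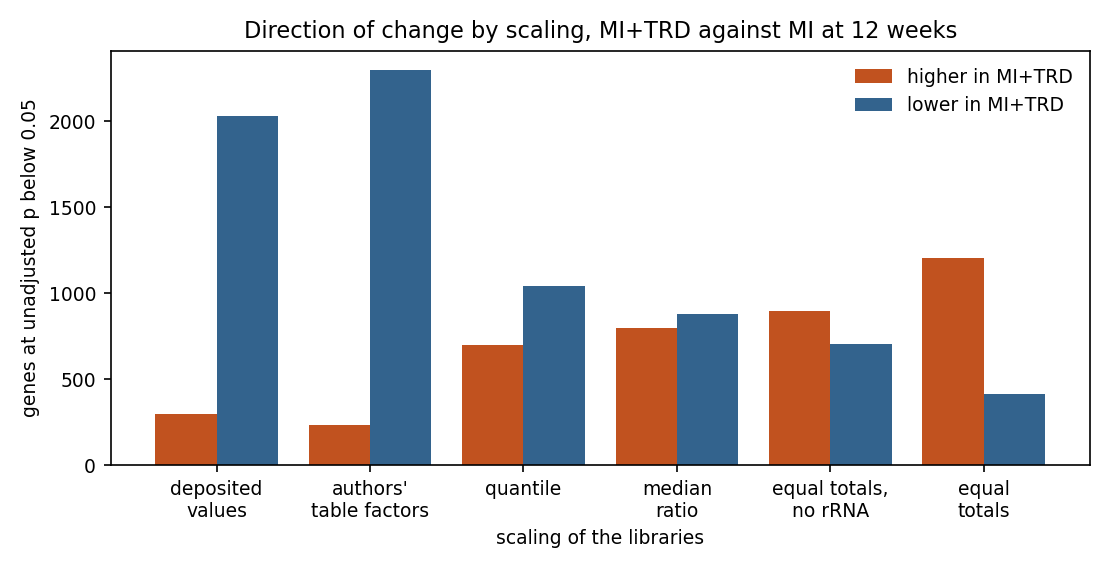
Genes at an unadjusted p below 0.05 (vertical axis, number of genes) that were higher (orange) or lower (blue) in MI+TRD than in MI at 12 weeks, under 6 scalings of the same 12 libraries (horizontal axis). The deposited values gave 298 higher and 2033 lower genes, and equal totals gave 1208 higher and 412 lower.

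Nuclear-encoded subunits of the respiratory chain, the machinery of oxidative phosphorylation, lay below other genes in MI+TRD at 12 weeks, with a median log2 fold change of −0.57 relative to all genes over 67 measured members. Cox4i1, a cytochrome c oxidase subunit, measured 984 ± 209 in MI and 590 ± 184 in MI+TRD (SD, n = 6 each). The complex I subunits Ndufs7 and Ndufb7 measured 122 ± 21.9 and 270 ± 53.9 in MI, and 77.4 ± 11.1 and 168 ± 41.5 in MI+TRD. No member passed over all genes with limma or DESeq2 and 59 were lower at an unadjusted p below 0.05, the other members passing in neither direction. Adjusted over the list alone, 59 were lower and 0 higher. The members lower at an unadjusted p were 88.1% of the list, against 19.1% of all genes on the deposited scale. Camera gave an adjusted p of 2.71e-17 for the list with its preset correlation, and an adjusted p = 0.866 with an estimated correlation.

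Citrate cycle genes, which feed electrons to that chain, had a relative median of −0.24 over 21 members, with 13 lower and 0 higher at an unadjusted p below 0.05 and 11 lower when adjusted over the list alone. Fatty acid uptake and oxidation genes, the main fuel pathway of the adult heart, had −0.18 over 40 members, with 16 lower and 0 higher, and 7 lower when adjusted over the list alone. No member of either list passed over all genes with limma or DESeq2. The citrate cycle enzyme genes Idh3g, Sdhb and Fh had relative log2 fold changes of −0.44, −0.39 and −0.35. Those of the electron transfer flavoprotein gene Etfb, the malonyl-CoA decarboxylase gene Mlycd and the nuclear receptor gene Esrra were −0.46, −0.38 and −0.41. Camera gave adjusted p-values of 0.000549 and 0.00921, and an adjusted p = 0.866 with an estimated correlation for both lists. Both camera calls ended without MI+TRD replicates 1, 4 and 5, at adjusted p-values of 0.0938 and 0.0653 and relative medians of −0.08 and −0.06. The fatty acid call also ended without MI replicate 3 (camera adjusted p = 0.0544), MI replicate 6 (0.0923) or MI+TRD replicate 6 (0.252), and without MI+TRD replicate 5 its median was −0.11. It ended as well with quantile normalization (0.0960) and with library weights (0.0851).

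Genes with a short genomic span moved with these lists. Relative to all genes, the median log2 fold change was −0.29 for 353 genes spanning up to 2 kb and 0.15 for 1410 genes spanning 50 to 100 kb. The short genes were lowest in MI+TRD replicates 1, 4 and 5, at −0.50, −0.33 and −0.33 (log2, median deviation from their mean over the libraries), while MI+TRD replicates 2, 3 and 6 had 0.19, 0.14 and −0.01. The respiratory chain score relative to the library median was also low in replicates 1, 4 and 5, between −1.18 and −0.99 against the MI mean, and was 0.05, 0.05 and −0.44 in replicates 2, 3 and 6. Hba2, an alpha-globin gene of red cells, measured 88.35, 233.7 and 464.7 in replicates 1, 4 and 5, 0.498 to 2.71 in the other MI+TRD libraries and 0.809 to 25.7 in MI. Over the 8 erythroid members, the score relative to the library median lay above the highest MI library in only 2 MI+TRD libraries. Genes at 0 reads numbered 119, 114 and 178 in replicates 1, 4 and 5, 13 to 46 in the other MI+TRD libraries and 28 to 75 in MI. Without these 3 libraries the median of the respiratory chain list was −0.10 (camera adjusted p = 0.0173), and with library weights it was −0.29.

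Markers of the epicardium and mesothelium, the surface lining of the heart, lay above other genes in MI+TRD, with a relative median of 1.34 over 11 measured members. Msln, which encodes the surface protein mesothelin, measured 0.593 ± 0.537 in MI and 12.7 ± 15.1 in MI+TRD (SD, n = 6 each). The keratin gene Krt8 measured 0.352 ± 0.207 and 2.82 ± 3.03, and the membrane glycoprotein gene Gpm6a measured 3.82 ± 2.58 and 7.91 ± 2.03. At an unadjusted p below 0.05, 6 members were higher and 0 lower. Adjusted over the list alone, 5 were higher, and none passed over all genes with limma, while DESeq2 called Upk1b, Krt8 and Msln (adjusted p = 0.00688, 0.0178 and 0.0422). Camera gave an adjusted p of 5.36e-07, and an adjusted p = 0.866 with an estimated correlation. Averaged per library relative to the library median, the score was −2.78 ± 0.17 in MI and −1.57 ± 0.90 in MI+TRD (SD, n = 6 each; exact permutation p = 0.00866, adjusted p = 0.139 over 16 marker and technical lists). On that relative scale all 6 MI+TRD libraries lay above the MI mean and 5 above the highest MI library. As plain levels, MI+TRD replicate 4 (0.46) lay below the MI mean of 0.63, and replicate 1 (0.74) below the highest MI library (0.79). The exact permutation p was 0.0325 for levels (adjusted p = 0.260) and 0.0649 for z-scores (adjusted p = 0.485). Over all 39 lists the relative score had an adjusted exact permutation p of 0.338. The relative median was 0.76 with the largest of 3 pseudocounts and 0.41 with the strictest filter on low values, settings that weigh down members with few reads.

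**Figure D2:**
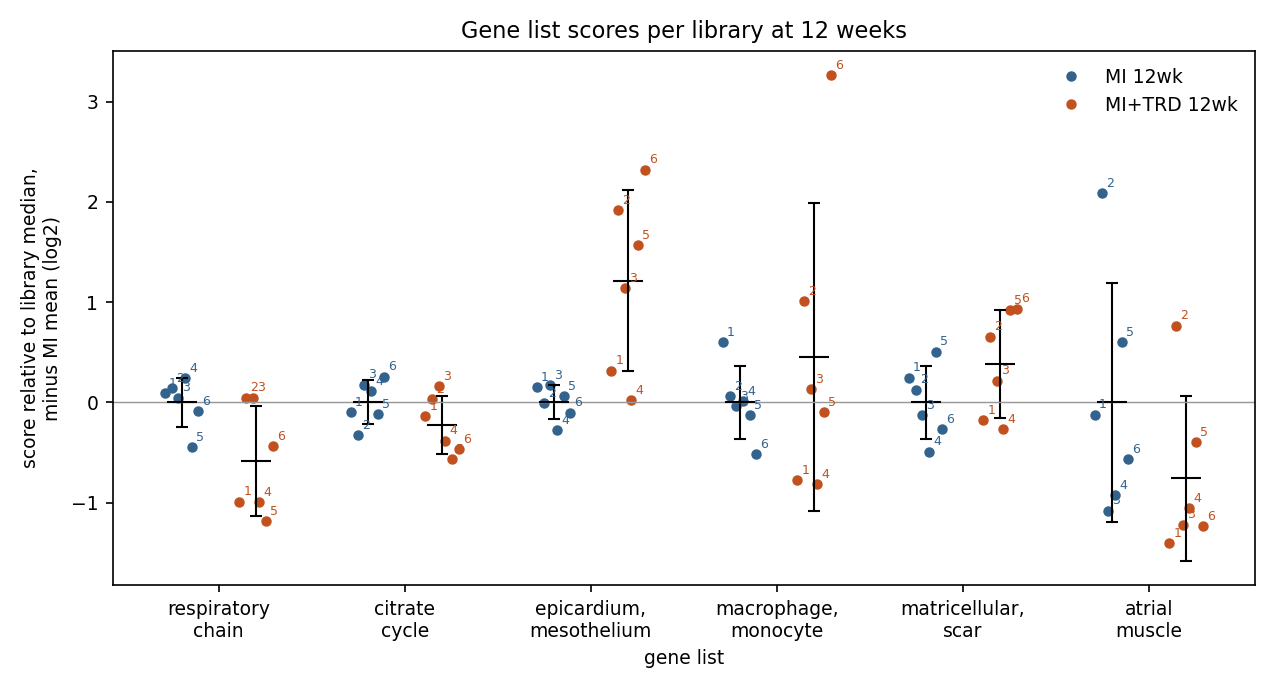
Mean log2 level of each gene list's members relative to the library median, minus the MI mean (vertical axis, log2), for MI (blue) and MI+TRD (orange) at 12 weeks, with each point 1 library with its replicate number and bars the mean and SD over 6 libraries. In the epicardial and mesothelial list the MI+TRD libraries ran from 0.03 to 2.32, and in the macrophage list MI+TRD replicate 6 stood at 3.27.

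The macrophage, matricellular, complement and chemokine lists lay above other genes in MI+TRD at 12 weeks, with wide spread between libraries. The macrophage and monocyte list had a relative median of 0.52 over 27 members, 0 of them higher or lower at an unadjusted p below 0.05. Its members Cd53, a leukocyte tetraspanin gene, and Fcgr2b, an inhibitory antibody receptor gene, measured 1.93 ± 0.790 and 0.514 ± 0.414 in MI, and 8.34 ± 14.9 and 9.49 ± 21.3 in MI+TRD (SD, n = 6 each). The matricellular and scar list had 0.31 over 33 members, with 2 higher and 0 lower, among them Omd at 1.10 (0.70 without MI replicate 4) and Ogn at 0.75. These small leucine-rich proteoglycan genes and Aspn, at 0.76, share overlapping spans on chromosome 17, so reads could be divided among them in an unknown way. The complement and coagulation list had 0.13 over 27 members, with 4 higher and 0 lower, including the central component C3 at 2.36 and the terminal component C6 at 2.11. The chemokine, cytokine and adhesion list had 0.20 over 42 members, with 2 higher and 1 lower; Il33, an alarmin, had 0.83 and the lymphatic chemokine gene Ccl21 −1.59. For each of these 4 lists 0 members passed with limma when adjusted over the list alone and 0 over all genes, while DESeq2 called C3 over all genes (adjusted p = 0.0178). C3 measured 1.87 ± 0.765 in MI and 30.9 ± 52.7 in MI+TRD (SD, n = 6 each), above the MI mean in 4 of 6 MI+TRD libraries. DESeq2 was not refitted with single libraries left out.

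Camera gave adjusted p-values of 0.000549, 0.000549, 0.00217 and 0.00921 for the macrophage, matricellular, complement and chemokine lists, and an adjusted p = 0.866 with an estimated correlation for all 4. MI+TRD replicate 6 stood apart in them: its macrophage score was 3.27 above the MI mean, and its level of Fn1, the fibronectin gene, was 1366 against 21.4 to 55.5 in the other MI+TRD libraries. Without it the relative medians were −0.09 for macrophage, −0.01 for complement and −0.04 for chemokine genes, with camera adjusted p-values of 0.965, 0.233 and 0.457, and 0.20 for matricellular genes (camera adjusted p = 0.00950), which had 0.52 without MI+TRD replicate 1. Single members also lay lower without MI+TRD replicate 6, at 0.39 for Cd53, 0.49 for Fcgr2b and 1.19 for C6. The complement call ended without MI+TRD replicate 2 as well (camera adjusted p = 0.0529), and the chemokine call without MI replicate 4 (0.0569), MI replicate 6 (0.103) or MI+TRD replicate 2 (0.0529). Over the libraries left out in turn, the medians ran from −0.01 (MI+TRD replicate 6) to 0.31 (MI+TRD replicate 4) for complement genes and from −0.04 (MI+TRD replicate 6) to 0.43 (MI replicate 1) for chemokine genes. They moved by over 1.5 times without any of MI replicates 1, 2 and 5 and MI+TRD replicates 1 and 3 to 6 for complement, and without any library but MI replicate 5 and MI+TRD replicates 2 and 3 for chemokine genes. With median ratio scaling the macrophage, complement and chemokine calls ended, at camera adjusted p-values of 0.0570, 0.0529 and 0.207. With equal totals all 4 ended, the matricellular call at 0.0514, and with quantile normalization the chemokine call ended at 0.0548. Without MI+TRD replicates 1, 4 and 5, a fit that keeps MI+TRD replicate 6, all 4 medians were further above 0. They were 1.49 for macrophage, 1.05 for complement, 0.91 for chemokine and 0.51 for matricellular genes (camera adjusted p = 2.05e-23, 5.15e-15, 2.78e-10 and 4.59e-08).

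Proliferation and red cell genes lay slightly above other genes. Cell cycle genes had a relative median of 0.14 over 27 members and erythroid genes 0.37 over 8, with 0 members of either passing at an unadjusted p below 0.05. The proliferation genes Top2a, Mki67 and Aurkb had relative log2 fold changes of 0.71, 0.73 and 0.73. The haem synthesis gene Alas2 had 0.50, and the alpha-globin genes Hba-a1 and Hba2 had 0.71 and 1.87. These are near-identical copies, and how reads were divided between them is not known without the counting rules. Camera gave adjusted p-values of 0.0177 and 0.0465 for these lists, and an adjusted p = 0.866 with an estimated correlation. The cell cycle call ended without MI replicate 6, MI+TRD replicate 2 or MI+TRD replicate 6 (camera adjusted p = 0.0546, 0.0599 and 0.423), and its median was 0.04 without MI+TRD replicate 6, 0.08 without MI replicate 4 and 0.22 without MI+TRD replicate 1. The erythroid call ended without any of MI replicates 2, 3 and 6 and MI+TRD replicates 2 to 6, at camera adjusted p-values from 0.0529 to 0.284, and its median was 0.24 without MI+TRD replicate 5, 0.57 without MI replicate 4 and 0.61 without MI+TRD replicate 1. Both calls ended with median ratio scaling (camera adjusted p = 0.137 for both) and with equal totals (0.258 and 0.187). Without MI+TRD replicates 1, 4 and 5 the cell cycle median was 0.46 (camera adjusted p = 9.07e-07), and the erythroid call ended at a median of 0.30 (0.124). The value of Hba2 was −1.69 in that fit, and without MI+TRD replicate 4 or 5 alone it was 1.13 or 0.95. Alas2 had 0.31 without MI replicate 6, 0.79 without MI+TRD replicate 1 and 0.20 without MI+TRD replicate 5, and Hba-a1 had 0.40 without MI+TRD replicate 5. In the complement and cell cycle lists the median log2 fold change before centring was −0.01 in both, while the mean was 0.35 and 0.07.

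Genes of cardiac stress and scar that were followed in any case gave 2 of 15 at an unadjusted limma p below 0.05, where 2331 of all 10655 genes had such a p. Neither of the 2 passed over all genes with limma or DESeq2. Nppb, the B-type natriuretic peptide gene, measured 306 ± 107 in MI and 150 ± 88.2 in MI+TRD, and the angiogenic factor gene Vegfa 614 ± 59.4 and 428 ± 81.4 (SD, n = 6 each; limma adjusted p = 0.133 for both). Nppa, the atrial natriuretic peptide gene, measured 2050 ± 2428 and 645 ± 808, a relative log2 fold change of −1.48 that was −0.95 without MI replicate 2 and −0.91 without MI+TRD replicate 1, and the atrial myosin light chain gene Myl7 ranged from 2.32 to 3170 in MI. The relative log2 fold changes were −0.29 for skeletal actin Acta1, −0.43 for the matricellular factor Ctgf (0.10 with atrial markers as a covariate), 0.07 for Tgfb1 and −0.23 for the stretch-responsive Ankrd1, which had 0.11 with quantile normalization. Those of the contractile genes Myh6, Myh7 and Atp2a2, the cardiac myosins and the calcium pump, were 0.07, 0.14 and 0.15. Without MI+TRD replicates 1, 4 and 5 these 3 values were −0.31, −0.18 and −0.19, and Myh7 had −0.14 with atrial markers as a covariate and −0.01 with library weights. Acta1 had −0.15, −0.56 and −0.19 without MI replicates 1, 2 and 6, and −0.57 and −0.14 without MI+TRD replicates 5 and 6. Ctgf had −0.22 and −0.69 without MI replicates 2 and 4 and −0.19 without MI+TRD replicate 1, and Ankrd1 had −0.14 without the last. Atp2a2 ran from 0.06 without MI+TRD replicate 4 to 0.33 without MI+TRD replicate 6. Leaving out 1 library turned the sign of Myh6 (MI replicate 5 or MI+TRD replicate 1 or 4, lowest −0.05), Myh7 (MI replicate 2 or MI+TRD replicate 5, lowest −0.08) and Tgfb1 (MI replicate 3 or 6 or MI+TRD replicate 6, lowest −0.07). Fn1 measured 24.0 ± 6.96 in MI and 256 ± 544 in MI+TRD (SD, n = 6 each), and the other scar genes had 0.63 for Col1a1, 0.31 for Col3a1, 0.82 for Postn and 0.52 for Timp1, each with an SD in MI+TRD above that in MI. Without MI+TRD replicate 6 they had 0.62 for Fn1, 0.11 for Col1a1, 0.06 for Col3a1, 0.30 for Postn and 0.01 for Timp1. Timp1 had 0.97 and 0.85 without MI+TRD replicates 1 and 4, 0.28 without MI+TRD replicate 2 and 0.33 without MI replicate 6.

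The other 29 lists did not pass camera, with adjusted p-values from 0.136 to 0.931. Relative medians below 0 were −0.34 for nerve and glia, −0.30 for lung, −0.23 for the hypertrophy and fetal program, −0.20 for adipocyte, −0.17 for atrial muscle, −0.10 for endothelium, −0.09 for heat shock, −0.09 for interferon response and −0.06 for smooth muscle and pericyte. Lymphocyte markers had −0.06, sarcomere −0.05, skeletal muscle −0.05, mechanosensing −0.05, glycolysis −0.05, circadian clock −0.04, immediate early genes −0.04, oxidative stress −0.04 and basement membrane −0.02. Relative medians above 0 were 0.28 for neutrophil, 0.18 for renin-angiotensin, 0.17 for angiogenic signalling, 0.17 for fibrillar collagens, 0.10 for Wnt signalling, 0.10 for calcium handling, 0.08 for TGF-beta signalling, 0.07 for MHC class II, 0.07 for matrix turnover, 0.04 for fibroblast and 0.01 for mast cell. The camera direction of the lymphocyte, clock and immediate early lists was up, against their medians. Leaving out 1 library turned the sign of 18 of these 29 medians. Without MI+TRD replicate 6 the medians were −0.08 for neutrophil, −0.02 for fibrillar collagens, −0.36 for MHC class II and −0.33 for lymphocyte markers, and their highest were 0.54 (without MI+TRD replicate 1), 0.27 (replicate 4), 0.27 (replicate 4) and 0.21 (replicate 3). Adipocyte markers ran from −0.40 without MI replicate 3 to 0.07 without MI replicate 2, and skeletal muscle from −0.40 without MI+TRD replicate 5 to 0.15 without MI+TRD replicate 1. Leaving out 1 library brought a call for the hypertrophy program (without MI+TRD replicate 5, camera adjusted p = 0.0150), smooth muscle (MI+TRD replicate 5, 0.00945), nerve and glia (MI replicate 3 or MI+TRD replicate 5, 0.0207 and 0.0150), calcium handling (MI+TRD replicate 6, 0.00950), neutrophil (MI+TRD replicate 1, 0.0400) and angiogenic signalling (MI+TRD replicate 2 or 6, 0.0226 and 0.0434). Nerve and glia was also called with equal totals (0.0152, or 0.0318 without ribosomal RNA) and with the span trend removed (0.0356, or 0.0289 after median ratio scaling). It was not called without the 3 libraries with atrial markers (camera adjusted p = 0.777), and its relative median over the 29 refits came as near 0 as −0.02. Without MI+TRD replicates 1, 4 and 5 calcium handling was called the opposite way, at −0.19 (camera adjusted p = 0.0194). That fit also called MHC class II at 1.02 (8.48e-07), neutrophil at 1.01 (8.66e-05), mast cell at 0.52 (0.0204) and immediate early genes at 0.38 (6.27e-05). It called matrix turnover at 0.31 (0.00892), fibrillar collagens at 0.28 (0.0120), fibroblast at 0.26 (0.0220), oxidative stress at 0.14 (0.000434) and smooth muscle at −0.24 (7.43e-06). None of the 16 marker and technical scores passed an adjusted exact permutation test, whether taken as levels, as z-scores or relative to the library median.

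In the authors' deposited table for 12 weeks, 5 genes were higher and 327 lower at a false discovery rate below 0.05, and 239 were higher and 2482 lower at an unadjusted p below 0.05, among 11283. Tnfrsf11b led the higher genes in the authors' deposited table, at a ratio of 7.30 (false discovery rate 0.0456), followed by the mannosidase gene Manea at 2.26, the hypoxia-response gene Hif1a at 1.62 and the condensin gene Smc4 at 1.73. The lower genes with the smallest p in the authors' deposited table were Traf2 at a ratio of 0.566 (false discovery rate 0.00657), Rex1bd at 0.446, Tcf15 at 0.498, Bod1 at 0.562 and Spns1 at 0.601. Of the 332 calls in the authors' deposited table, 330 were among the genes tested with limma, and all 330 had a limma unadjusted p below 0.05 in the same direction, with a limma adjusted p of 0.133 at the lowest. Across genes, the log2 ratios of the authors' deposited table and the limma log2 fold changes had a Spearman correlation of 0.973.

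The 6-week comparison asked the same question at the earlier time. In the authors' deposited table, genes of macrophages and of the scar matrix were among the higher genes with the smallest p. Mmp12, a macrophage elastase gene, stood at a ratio of 78.5, the integrin gene Itgam at 10.1, the NADPH oxidase gene Cybb at 7.68, the haem oxygenase gene Hmox1 at 6.05 and the lysosomal glycoprotein gene Gpnmb at 9.35 in the authors' deposited table. Matrix genes there were Fn1 at 8.48, Thbs2 at 2.05, Mmp2 at 1.83 and the tenascin gene Tnn at 29.4 in the authors' deposited table. The smallest p among higher genes belonged to the secreted C1q-related gene C1qtnf3, at a ratio of 11.2 in the authors' deposited table. None passed a false discovery rate of 0.05 in the authors' deposited table, where the lowest was 0.0989, with 499 genes higher and 462 lower at an unadjusted p below 0.05 against 564 in all by chance. MI means at 6 weeks in the authors' deposited table were only 0.1404 for Mmp12, 0.08195 for Tnn and 0.148 for C1qtnf3. The size of the ratios of these genes is therefore uncertain. At 12 weeks a count of 0 allowed up to 3 reads, worth 0.118 to 0.162 deposited units depending on the library, besides the 1 step added to every value. That limit was not worked out for 6 weeks.

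The lower genes with the smallest p at 6 weeks were Mapk12 at a ratio of 0.622, the actin-binding Coro6 at 0.664, the transporter gene Abca8a at 0.606, the junction adaptor gene Afdn at 0.680 and the glycine cleavage gene Amt at 0.528 in the authors' deposited table. Next to them, the authors' deposited table listed Fam126b at 0.312, Zfp775 at 0.640, Trim50 at 0.584, Usp28 at 0.652 and Map4k2 at 0.682. Mapk12 and Coro6 were also lower at 12 weeks in the authors' deposited table, at ratios of 0.599 and 0.650 and a false discovery rate of 0.0381 each. Scar genes at 6 weeks had ratios of 4.12 for Col1a1, 2.51 for Col3a1, 9.48 for Postn and 2.69 for Timp1 in the authors' deposited table, and the contractile genes Myh6, Myh7 and Atp2a2 had 0.966, 0.905 and 0.962.

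As groups, 24 macrophage markers of 30 were higher and 0 lower at 6 weeks at an unadjusted p below 0.05 in the authors' deposited table, with a median log2 ratio of 1.67 relative to all genes. The same table, the authors' deposited table for 6 weeks, gave 10 of 12 MHC class II genes (relative median 1.56), 11 of 13 fibrillar collagens (0.87), 19 of 34 matricellular genes (0.77), 13 of 28 complement genes (0.84) and 17 of 36 matrix turnover genes (0.53) as higher. Each of these 6 medians lay above all of 10000 random lists matched on level in the authors' deposited table, which describes that table and is no test across rats. In all, 24 of 39 lists lay outside the central 95% of random lists at 6 weeks, 15 above and 9 below, by the authors' deposited table. The endothelial list, with 7 lower and 1 higher of 25 and a relative median of −0.32, and the erythroid list, at −0.61, were among those below in the authors' deposited table.

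**Figure D3:**
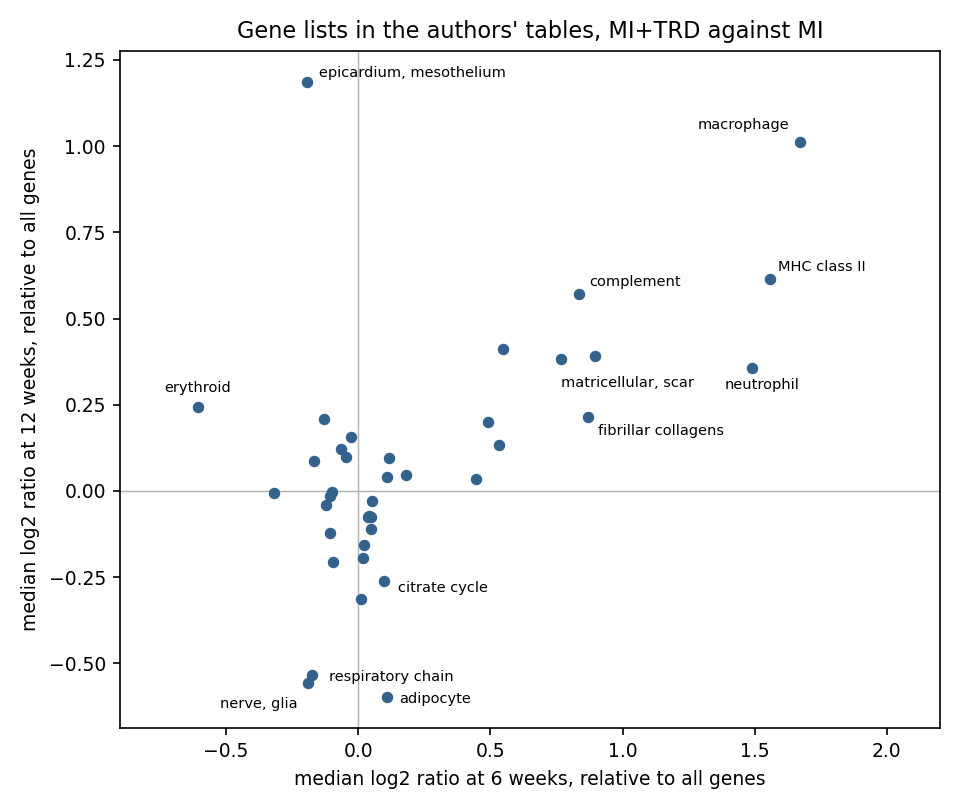
Median log2 ratio of MI+TRD to MI for each of 39 gene lists, relative to all genes, in the authors' deposited tables at 6 weeks (horizontal axis) and 12 weeks (vertical axis). Each point is 1 list; respiratory chain genes stood at −0.17 and −0.53, and epicardial and mesothelial genes at −0.19 and 1.19.

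Both times could be set side by side only through the authors' deposited tables. Over 11283 genes the log2 ratios at 6 and 12 weeks in the authors' deposited table of each time had a Spearman correlation of 0.245 across genes, which are not independent replicates. At an unadjusted p below 0.05 at both times, the authors' deposited tables shared 18 higher genes, against 10.6 for independent lists, and 159 lower genes, against 101.6. Of 187 genes past that p at both times in the authors' deposited tables, 177 (94.7%) had the same sign. At 12 weeks 14 lists lay outside the central 95% of random lists in the authors' deposited table, 9 of them on the same side at both times and 3 on opposite sides. Those 3 were citrate cycle genes, at 0.10 and −0.26, angiogenic signalling, at −0.13 and 0.21, and epicardial and mesothelial genes in the authors' deposited tables. Macrophage genes had 1.67 at 6 weeks and 1.01 at 12 weeks, respiratory chain genes −0.17 and −0.53, and epicardial and mesothelial genes −0.19 and 1.19 in the authors' deposited tables. For macrophage genes at 12 weeks the limma relative median, 0.52, was −0.09 without MI+TRD replicate 6. Also on the higher side at both times were complement, chemokine, MHC class II, fibrillar collagen, matrix turnover and matricellular genes. Without that library their limma relative medians were −0.01, −0.04, −0.36, −0.02, −0.03 and 0.20, in that order. On the lower side at both times, respiratory chain genes had −0.59 without it and nerve and glia −0.17. Whether any gene or list differed between the times was not tested, since the tables hold no values per library.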

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

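Of the tests weighed here, those of the scaling, of the span trend removed after it, of the sarcomere genes and of the splits by adjusted p, unadjusted p and gene lists were chosen only after the result was seen, as were the fits without the libraries with atrial markers or low in short genes. In 16 of 248 groups of 6 values, 1 library lay far from the others, where chance alone gives about 1 in 20 groups, or 12.4. MI+TRD replicate 6 held 6 of them. Its normalized counts were 1366 for Fn1 (21.4 to 55.5 in the other MI+TRD libraries), 1073 for Col1a1 (78.8 to 194.7), 38.7 for Cd53 (1.20 to 3.35) and 46.15 for Hif1a (20.18 to 26.25). Its score relative to the library median was 1.16 for matrix crosslinking and turnover (0.01 to 0.37) and 5.01 for sarcomere and Z-disc genes (5.47 to 5.69). MI+TRD replicate 1 had 2442 for Ankrd1 (3493 to 4165) and 24.9 for Hspe1 (35.1 to 39.5), and MI+TRD replicate 3 had 3.11 for Zdhhc20 (4.26 to 4.71). Among MI libraries, replicate 4 had 63.0 for Pmpca (45.8 to 51.5), 129 for Esrra (69.9 to 87.7) and 2885 for Mybpc3 (2036 to 2299). MI replicate 2 had 15.1 for Traf2 (11.4 to 12.5) and 359.9 for Acta1 (893.6 to 1433). MI replicate 1 had 433 for Tcap (363.7 to 388) and a neutrophil score of −1.97 (−3.89 to −3.34).

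The first pattern weighed is the excess of lower genes in MI+TRD at 12 weeks, 87.2% of those at an unadjusted p below 0.05. The real split gave 2331 genes at that p, and 3 of 100 splits, the real one included, gave as many (highest other 2785); as this is 1 of 4 such counts, 3 of them chosen after the result was seen, and 6 of 100 splits reached the 1676 genes after median ratio scaling (highest other 2534), chance is not excluded. With median ratios the share of lower genes was 52.4%, and removing the trend with gene span after that moved it by 4.54 points to 47.8%. Both settings centre the typical gene, which brings the balance near even whatever the cause, so neither value decides. The scaling of the deposited values, a trend with gene span and a biological shift of most transcripts in 1 direction cannot be told apart, since the values hold no external standard.

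The second pattern is the lower respiratory chain list, where chance is not excluded. A trend shared by all genes of like genomic span is argued against as the whole cause. The list's median of −0.71 (log2, not centred) lay at percentile 0 of 10000 random lists matched on span and level, whose medians ran from −0.36 to −0.20. These lists were drawn gene by gene, so their range leaves out the correlation between members (estimated at 0.749) and is no test across libraries. Transcript length was not matched, so a trend with it stays open. A smaller share of cardiac muscle would lower sarcomere genes too. Their relative median was 9.21% of that of the respiratory chain (−0.05 against −0.57, bootstrap interval over members −12.97 to 35.6). Over all libraries this argues against a fall of like size in both lists, but the interval leaves out the spread between rats. On the deposited scale 36.0% of sarcomere genes were lower at an unadjusted p below 0.05, against 19.1% of all genes. The exact permutation p of their score was 0.00866 for z-scores and 0.682 relative to the library median. A smaller share of muscle as part of the cause is therefore not excluded. Without MI+TRD replicates 1, 4 and 5 the sarcomere median was 150.1% of that of the respiratory chain (−0.15 against −0.10, interval 86.8 to 305.2). A smaller share of muscle stays open for the smaller difference left there. The exact permutation p of the score was 0.04762, under the bound set beforehand, but that bound ignored that the list was singled out among 39, over which the adjusted p is 0.654. RNA quality in MI+TRD replicates 1, 4 and 5, without which the relative median was −0.10 (camera adjusted p = 0.0173), stays open. So does an effect on mitochondrial genes of the device or of the second operation, which only MI+TRD rats had.

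The third pattern is the higher epicardial and mesothelial score. Atrial tissue in some libraries is argued against, as 89.6% of the difference was left without the 3 libraries with Myl7 above 100 (1.09 of 1.22; exact permutation p = 0.0635). MI+TRD replicate 6 alone is argued against as well, with 80.2% left without it (0.97, exact permutation p = 0.00866). That covers 1 library only. Against the MI mean, MI+TRD replicates 2, 3 and 5 had epicardial scores of 1.92, 1.14 and 1.57 and matricellular scores of 0.66, 0.22 and 0.92. Replicates 1 and 4 had 0.32 and 0.03, and −0.18 and −0.27. MI replicate 5, at 0.51 in the matricellular list, had an epicardial score of 0.06. Whether the amount of scar sampled lay behind the difference was not tested and stays open. The exact permutation p over all libraries was 0.00866, under the bound set beforehand, which ignored the choice among 16 lists, and the adjusted p of 0.139 does not exclude chance. That score was taken relative to the library median. As levels and as z-scores the exact permutation p was 0.0325 and 0.0649, the second of them not under the bound. How much of the heart's surface lining was sampled was not tested and stays open, as does an effect of the device or of the second operation, which only MI+TRD rats had; at 6 weeks, after the same operation, the list stood at −0.19 in the authors' deposited table (percentile 1.14 of random lists, 0 members higher and 1 lower).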

How the results depend on the processing

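Of these tests, the factors of the authors' table, totals without ribosomal RNA, the fits with atrial markers or without the libraries they mark, the removal of the span trend and the fit without 3 libraries low in short genes were chosen after the data were seen. At an adjusted p below 0.05 no limma alternative called a gene and DESeq2 called 21; 2331 genes had an unadjusted p below 0.05. At an adjusted p below 0.1 limma called 0 over all libraries, 1086 without MI+TRD replicate 2, 1155 without MI+TRD replicate 6, 743 with the factors of the authors' table and 3 without the 3 libraries low in short genes, and DESeq2 called 85. In the authors' deposited tables, 961 genes had an unadjusted p below 0.05 at 6 weeks and 2721 at 12 weeks, and Pearson's r between the times was 0.436. The 10 lists called became 5 with median ratios, 5 with equal totals, 6 with equal totals without ribosomal RNA, 20 without MI+TRD replicates 1, 4 and 5, 0 with an estimated correlation and 0 with fry; leaving out each library gave 6 (without MI replicate 6 or MI+TRD replicate 6) to 12. The cause was not tested. The respiratory chain and epicardial lists passed camera in the same direction in all 29 refits. Of 2636 alternative values of 91 named genes, 2619 kept their direction and side, 17 in 8 genes had the opposite sign, and 0 passed limma's adjusted threshold. Relative log2 fold changes turned with quantile normalization for Ankrd1 (0.11) and Mybpc3 (0.0314), with library weights for Myh7 (−0.0103), and with atrial markers as a covariate for Ctgf (0.10) and Myh7 (−0.14). Without the 3 libraries low in short genes, Atp2a2 had −0.19, Hba2 −1.69, Myh6 −0.31 and Myh7 −0.18. Leaving out each library gave −0.088 to 0.75 for the macrophage median, −0.0481 to 0.27 for Myh6, −0.0843 to 0.27 for Myh7 and −0.0712 to 0.21 for Tgfb1; the cause was not tested. The replicate numbers were not taken to pair the libraries, since same-numbered libraries had correlations of −0.330 to 0.327, over 0.1 in 4 of 6 pairs and not in all; 7 of 12 libraries correlated best with their own number, where chance gives about 2, a hint of pairing from the data, not the design. With the replicate block 0 genes and 10 lists were called, with 272 genes higher and 1835 lower at an unadjusted p below 0.05. Depth limits low genes such as Krt8, near 0.352 in MI. A count of 0 allows up to 3 reads, worth 0.118 to 0.162 deposited units depending on the library, besides the 1 step added to every value.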

Other observations

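The tests of splits below, and the fits without MI+TRD replicates 1, 4 and 5 or without the libraries with atrial markers, were chosen after the result was seen. None of the endothelial, interferon, sarcomere, hypertrophy, glycolysis, angiogenic and heat shock lists passed the set test at 12 weeks over all libraries, and none of their members passed limma's test over all genes, while DESeq2 called Myh7b of the hypertrophy list (adjusted p = 0.0178). On the deposited scale 2033 of 10655 genes (19.1%) were lower in MI+TRD at an unadjusted p below 0.05, and whether a list held more than that share was not tested beyond the set test. Among endothelial markers, 8 of 25 (32.0%) were lower and 0 higher at that p, and 6 were lower adjusted over the list alone (camera adjusted p = 0.283). The fatty acid carrier gene Fabp4 measured 152 ± 30.8 in MI and 96.3 ± 24.0 in MI+TRD (SD, n = 6 each), the secreted vessel factor gene Egfl7 35.4 ± 10.4 and 19.2 ± 7.67, and the junction gene Esam 76.6 ± 16.4 and 52.5 ± 12.5. Among interferon-response genes, 8 of 31 (25.8%) were lower and 0 higher, with 1 lower adjusted over the list alone. Bst2, which tethers virus particles, measured 66.0 ± 12.95 and 35.0 ± 15.5, and the interferon regulatory factor genes Irf7 and Irf9 measured 22.4 ± 5.03 and 8.49 ± 1.06 in MI and 15.5 ± 3.43 and 5.98 ± 1.40 in MI+TRD.

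Of 25 sarcomere and Z-disc genes 9 (36.0%) were lower at an unadjusted p below 0.05 and 2 adjusted over the list alone, with Tcap, the titin cap, at 382 ± 26.4 and 213 ± 112 and cardiac troponin C gene Tnnc1 at 610.05 ± 112 and 400.4 ± 84.9 (SD, n = 6 each). The hypertrophy, glycolysis and heat shock lists lay near the share of all genes, at 21.1%, 17.6% and 21.2%. In the hypertrophy and fetal program 4 of 19 were lower, all 4 adjusted over the list alone, among them the calcineurin regulator gene Rcan1 at 433 ± 50.4 and 293.9 ± 89.6 and the Z-disc gene Csrp3 at 866 ± 216 and 544 ± 169. In glycolysis and glucose use 6 of 34 were lower, with the insulin-responsive transporter gene Slc2a4 at 223 ± 37.1 and 153 ± 31.1 and the muscle phosphoglycerate mutase gene Pgam2 at 379 ± 77.2 and 237 ± 46.8. In angiogenic signalling 1 was higher and 4 (12.9%) lower of 31: Hif1a had a relative log2 fold change of 0.85, while Vegfa, a target of its protein, had −0.40 and the Notch ligand gene Dll4 −0.27. In the heat shock and unfolded protein list 1 was higher and 7 lower of 33, with the chaperone genes Canx at 0.63, Manf at −0.75 and Hspe1 at −0.45. Without MI+TRD replicates 1, 4 and 5, which leaves 3 of those libraries, camera called the endothelial list at a relative median of −0.25 (adjusted p = 8.73e-05), the sarcomere list at −0.15 (0.00885) and the angiogenic list at −0.19 (0.0433), opposite to its 0.17 over all libraries. Without the 3 libraries with atrial markers it called the heat shock list at −0.20 (0.0399) and the angiogenic list in its upward direction, at 0.17 (0.0302).

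Other splits of the 12 libraries bear on how far the counts can be read. At an adjusted p below 0.05, all 100 splits gave at least the real count of 0 genes by limma (2331 at an unadjusted p, 0 by edgeR, 21 by DESeq2), which any split must reach, so that comparison decides nothing. Of the 99 other splits 3 called any gene, and the highest gave 271. A structure of the libraries that does not follow the groups may lie behind a split with 271 calls, as may chance among the splits drawn, and neither was tested. For gene lists, 72 of 100 splits gave at least the real count of 10, with 24 the highest other, so chance is not excluded for that count. The set test with its preset correlation thus called lists readily when the libraries were divided without regard to the groups.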
